A study of Phaeodactylum tricornutum with 6 samples.

How the data were processed

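Polyadenylated RNA from whole cells of Phaeodactylum tricornutum was sequenced for 6 samples, 3 from nitrogen-replete (0.88 mM nitrate) and 3 from nitrogen-starved cultures after 48 h. The labels describe 3 biologically independent cultures, each divided between both media, and number the samples of each group, without saying that equal numbers mark parts of one culture. Samples were grouped by the nitrogen treatment in their labels. Per the submitters' processing notes, the authors used DESeq 1.10.1. The read aligner, the counting method and the genome build are not given in the sources used here.

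The data are a single table of the authors' own comparison with 10402 genes. Per the file headers, the authors deposited the mean of normalised read signal over all samples and in each group, the fold ratio of the starved over the replete mean, its log2, a p-value and an adjusted p-value. The group means are reads divided by size factors, so they carry no correction for gene length. The ratio and the log2 were checked to follow from the means. The deposited adjusted p-values were recomputed with the Benjamini-Hochberg method over 10234 genes with a p-value, and differed by at most 2.14e-07. The other 168 genes have means of 0 in both groups and no p-value. A further 47 genes are listed at 0 in the starved group only and 54 in the replete group only.

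Gene identifiers were matched to the locus tags of the reference table for assembly ASM15095v2, which was used only for gene names and for which genes neighbour each other. Of 10402 identifiers, 10181 matched a locus tag and 610 had a symbol, 608 of them tested. The reference table gives symbols and no product descriptions, and identifiers without a symbol were left unnamed.

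Calls are those of the authors at an adjusted p under 0.05, as fixed before the data were examined for a table without values per sample. The genes named were also set by a fixed rule. It takes the 10 largest increases and 10 largest decreases among called genes with a symbol, a finite fold change and a mean of at least 100 in the higher group. It adds, for each list tested, up to 3 called members with the largest absolute log2 fold change and an overall mean of at least 50, the most abundant member of each list by its mean over both groups, the 5 most abundant genes of each group, and 2 identifiers each way without a symbol. It takes 134 genes, of which most are named. The few outside it are said to be named after their values were seen, and lists under the minimum size of 5 are given gene by gene.

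Gene lists had been fixed as 32 word patterns on product names. Since the reference holds symbols, 3 patterns matched genes (light-harvesting proteins, cell cycle and DNA replication, chaperones and heat shock) and 29 matched none, among them those on nitrogen uptake. For this reason 38 lists of symbols were written from the symbols alone before their values were looked at, and 33 of them had at least 5 tested genes. They were added after the table had been opened. The share of members called higher or lower was compared with that of the tested genes with a symbol outside the list by Fisher's exact test (two-sided), adjusted with the Benjamini-Hochberg method over 66 tests for the symbol lists and 6 for the patterns. Each median log2 fold change was set beside 10000 random lists of the same size, matched on 20 bins of the mean. They were drawn from the tested genes with a symbol, the list's own members included. Genes at 0 in a group entered medians at a limit of 3 reads over the group. Of the symbol genes 44.2% were called lower, against 28.2% of all tested genes, so the lists were also tested against all other tested genes.

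Whole reads per library were recovered from the group means. A group mean is the sum of whole reads in 3 libraries, each times a constant set by the size factor. These constants were found from the smallest values, and for every gene with a group mean above 0 and under 500 exactly 1 combination of whole reads gave the 10 deposited digits: 8317 of 8317 genes in the replete and 8371 of 8371 in the starved group. Random values decoded in 0% of cases. In simulated data 99.2% of 1994 genes were decoded to the true reads. The size factors were 1.36, 1.18 and 1.01 for the replete libraries and 1.04, 0.94 and 0.655 for the starved ones. The 7925 genes recovered in both groups exclude the most abundant genes and hold 3 of the 25 light-harvesting genes, and the libraries carry no replicate numbers. Total reads were estimated as the size factor times the sum of group means, 4591034 in the replete and 4205271 in the starved group. Values given as mean ± SD with n = 3 come from these recovered reads divided by size factors.

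As an analysis added after the data were seen, limma 3.58.1 in R 4.3.3 was fitted to log2 of the recovered normalised reads with a pseudocount of 1, for 7109 genes with an overall mean of at least 10, with a mean-variance trend and Benjamini-Hochberg adjustment. Fold changes from this fit are on the log2(value + 1) scale. On simulated reads for these 7109 genes, 77 of 100 genes changed 2-fold and 100 of 100 changed 4-fold were called in the right direction, with 10 unchanged genes called. The simulation gave every gene and library a dispersion of 0.03, had no library standing apart and changed few genes. Its counts need not hold for the real libraries, where 1 starved library stood apart and most tested genes were called. Lists with at least 5 recovered genes were tested with camera. For 18 lists, the median log2 difference of starved library C from starved libraries A and B was set beside 10000 random lists matched on the mean (two-sided p, Benjamini-Hochberg adjusted). The list test was checked on 608 genes with shuffled calls, where 20 shuffles gave 0 lists past the threshold and a planted list of 12 was found. The neighbour correlation was checked on 9102 simulated values, where a planted correlation read 0.405 and none read 0.0052.

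Alternatives fixed before the data were examined were other thresholds, a minimum change, a filter on the mean, Holm adjustment, other backgrounds, other scalings, a pseudocount of 0.1 and leaving out each sample. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, and figures matplotlib 3.10.9. Limits for 0 reads and chi-square values cover counting error only.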

Results

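Polyadenylated RNA was sequenced from whole cells of Phaeodactylum tricornutum, a marine diatom with a plastid of red algal descent, strain Pt1 8.6. Independent axenic cultures in exponential growth, 3 in all, were washed in medium without nitrogen and each was split into 2 parts. One part received 0.88 mM nitrate and the other no nitrogen source, and both were grown for 48 h. The 6 samples form a nitrogen-replete and a nitrogen-starved group of 3 each, and their comparison asks which transcripts differ after nitrogen withdrawal. The values are group means of reads normalised by size factors, with the authors' own comparison of the groups. Reads per library were recovered arithmetically for 7925 genes of low and medium abundance, and the libraries of each group are called A to C in order of size factor, since they cannot be tied to the replicate numbers of the labels. Estimated library totals were 6253762, 5433147 and 4628517 reads in the nitrogen-replete libraries and 4367672, 3951473 and 2754595 in the nitrogen-starved ones. A gene with no read in a group could have a group mean of up to 0.844 normalised reads in the replete and 1.14 in the starved group, where counting error alone is considered.

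A majority of the genes tested differed between nitrogen-starved and nitrogen-replete cultures, and antenna genes of the light-harvesting complexes had the largest decreases among genes with a symbol. Of 10234 genes tested, the authors' deposited table placed 2729 higher and 2891 lower in nitrogen-starved cultures at an adjusted p under 0.05, together 54.9% of those tested. An absolute log2 fold change of at least 1 was met by 1669 of the higher and 2061 of the lower genes in the authors' deposited table. Among genes above 0 in both groups, 118 were called at least 8-fold higher and 313 at least 8-fold lower in the authors' deposited table. The calls used the authors' DESeq adjusted p. Scaling both groups to one total would shift every log2 fold change up by 0.13, and centring on the median gene would shift it down by 0.05. None of the called genes with a finite fold change turned its sign under either scaling. Shifts this small could hardly turn the sign of a called gene, so this does not test the normalisation.

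The largest named decreases, ranked among genes with a symbol, were Lhcf8 (log2 fold change -8.31, adjusted p = 2.96e-170) and Lhcf5 (-8.18, adjusted p = 1.34e-193) in the authors' deposited table, both of them fucoxanthin chlorophyll proteins of the light-harvesting antenna. In the authors' deposited table, Lhcf3 fell to a log2 fold change of -7.41, Lhcf4 to -7.14, the light-harvesting-like LHL1 to -6.80 and the triose phosphate translocator gene Tpt3 to -6.53. FABD, the malonyl transferase of plastid fatty acid synthesis, fell from 349.7 ± 8.01 to 3.93 ± 3.40 normalised reads (mean ± SD, n = 3), and FTHFS, formate-tetrahydrofolate ligase, from 382 ± 16.4 to 5.00 ± 2.41. FABD read 0.963, 3.19 and 7.63 in starved libraries A, B and C, so the starved mean rests largely on library C. Lhcf12 and Lhcr11 completed the 10, with log2 fold changes of -6.20 and -6.18 in the authors' deposited table. Among genes without a symbol, PHATRDRAFT_34932 fell most, from 482 ± 41.4 to 1.34 ± 1.56 normalised reads (mean ± SD, n = 3), followed by PHATRDRAFT_32071, from 397 ± 30.4 to 1.69 ± 1.18. Starved libraries A, B and C held 0.963, 0 and 3.05 normalised reads of PHATRDRAFT_34932 and 0.963, 1.06 and 3.05 of PHATRDRAFT_32071. These means lie near the limit for 0 reads in the starved group (1.14), so the higher values in library C may be counting error.

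Named increases were smaller. GEL1 rose from a group mean of 99.7 to 979 normalised reads (9.82-fold, adjusted p = 1.28e-10) in the authors' deposited table. The ferric reductase genes FRE4 and FRE3 rose by log2 fold changes of 2.86 and 2.39, and CPS-II, a carbamoyl phosphate synthase, by 2.41 (adjusted p = 1.95e-28) in the authors' deposited table. SMP1 rose by 2.61 with the highest adjusted p of the 10, 0.00432 in the authors' deposited table. The others were BMS1, which is required for small ribosomal subunit assembly, at 2.60, SAS1 at 2.57, RPC17 at 2.56, helicase_6 at 2.89 and the nucleotide exchange factor gene GrpE (PHATRDRAFT_12896) at 2.49, all from the authors' deposited table. A more abundant gene of the same symbol, GrpE (PHATRDRAFT_bd1725), was called lower (-2.31) in the authors' deposited table and is named after its value was seen. Per library, SAS1 went from 64.1 ± 1.44 to 381 ± 59.4 and FRE4 from 63.9 ± 1.98 to 465 ± 113 normalised reads (mean ± SD, n = 3). Genes without a symbol reached larger increases: PHATRDRAFT_54101 rose from a group mean of 4.14 to 2283 in the authors' deposited table (log2 fold change 9.11, adjusted p = 5.89e-23).

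One unnamed gene, PHATRDRAFT_26029, became the most abundant transcript of the starved cultures, at a group mean of 115523 against 249 in replete cultures (log2 fold change 8.86, adjusted p = 1.07e-37 in the authors' deposited table). It took 2.75% of the summed starved means. The next in rank in the starved group was PHATRDRAFT_23497 at 59628, up from 28002 in the authors' deposited table. PHATRDRAFT_31433, PHATRDRAFT_20424 and PHATRDRAFT_52619 followed, with log2 fold changes of 2.82, 2.97 and 3.27 in the authors' deposited table. In replete cultures PHATRDRAFT_55230 (61011, falling to 26027) led the authors' deposited table, with 1.33% of the summed means. It was followed there by the chaperone genes HSP70A (57906), HSP20B (54687) and HSP20A (46115), and by PHATRDRAFT_51134 at 33463, in the authors' deposited table. The 10 most abundant genes took 7.90% of the summed means in replete and 9.63% in starved cultures, and the 100 most abundant 26.0% and 25.2%, values that carry no test.

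Light-harvesting genes fell almost as a block. Of 25 genes matched by the light-harvesting pattern, the authors' deposited table called 22 lower and 2 higher, and adjusted over the list alone the counts were also 22 and 2. Their median log2 fold change was -4.96, below all 10000 random lists matched on abundance (95% of random medians between -2.08 and -0.19), and the share called lower exceeded that of other genes with a symbol by Fisher's exact test (two-sided, adjusted p = 3.1e-05). All 16 Lhcf antenna genes were called lower in the authors' deposited table (median -5.43, range -8.31 to -2.89, Fisher's exact test adjusted p = 0.00011). Of the 5 Lhcr genes, related to the antenna of photosystem I, 4 were called lower (Fisher's exact test adjusted p = 0.465), led by Lhcr11, Lhcr12 (-5.29) and Lhcr4 (-4.92) in the authors' deposited table. The exception, Lhcr8, named here after its value was seen, had means of 83.3 ± 11.5 replete and 87.6 ± 38.4 starved normalised reads (mean ± SD, n = 3). It read 121, 95.8 and 45.8 in starved libraries A, B and C, and limma's fit called it higher without starved library C (adjusted p = 0.0479) and not with all libraries (adjusted p = 0.944). The Lhcx genes, whose products act in photoprotection, split: Lhcx1 (-4.35) and Lhcx2 (-4.38) fell, while Lhcx3 (1.27) and Lhcx4 (1.36) rose, in the authors' deposited table. Lhcx3 went from 59.3 ± 21.0 to 143 ± 12.5 and Lhcx4 from 49.0 ± 5.14 to 125 ± 15.8 normalised reads (mean ± SD, n = 3). The counting method is not given in the sources used here, so reads shared between similar members of this family could move values among them.

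**Figure D1:**
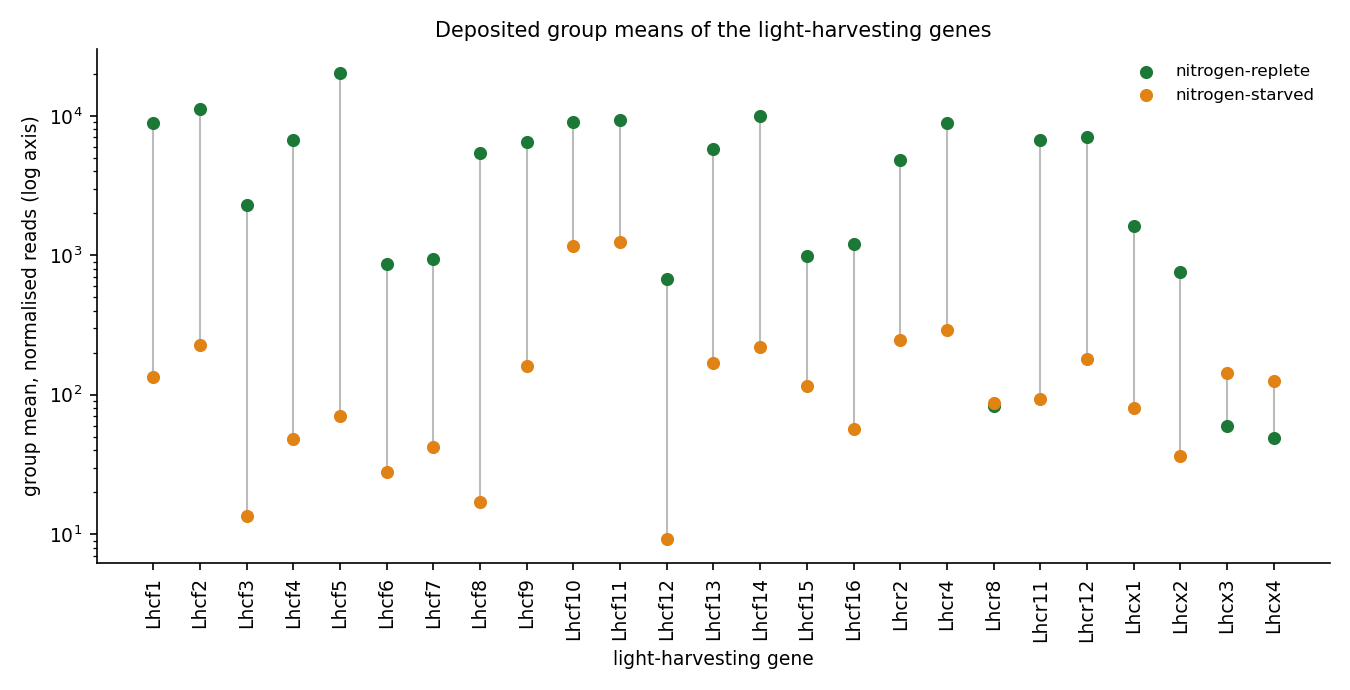
Group means (normalised reads, log axis) of the 25 light-harvesting genes in nitrogen-replete (green) and nitrogen-starved (orange) cultures; each grey line joins the means of 1 gene and no spread is drawn. All 16 Lhcf genes lie lower in starved cultures, and Lhcx3 and Lhcx4 lie higher.

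Genes of chlorophyll synthesis were lower in starved cultures. Of 12 genes of tetrapyrrole and chlorophyll synthesis, 11 were called lower in the authors' deposited table, with a median log2 fold change of -2.11 (Fisher's exact test adjusted p = 0.0271). With only genes of a mean of at least 50 in the test, this call was lost (adjusted p = 0.055). The steepest were hemE, uroporphyrinogen decarboxylase (-4.57), chlM, a methyltransferase of chlorophyll synthesis (-3.44) and HemF_2 (-3.24) in the authors' deposited table, and CHLH, a subunit of magnesium chelatase and the most abundant by the mean over both groups, fell by 5.38-fold. HemF_2 read 0.963, 2.13 and 48.9 in starved libraries A, B and C, so its starved mean, fold change and rank rest largely on library C. PPO was the only member not called, at 0.16 in the authors' deposited table, and is named here after its value was seen. Of 10 genes of carotenoid synthesis and the xanthophyll cycle, 6 were called lower and none higher in the authors' deposited table, a share that did not pass the test against other symbol genes (Fisher's exact test adjusted p = 0.602). ZEP1, a zeaxanthin epoxidase, fell by 7.99-fold, CRTISO5 by 4.42-fold and VDL2 by 4.32-fold in the authors' deposited table, while LUT1-2, the most abundant by the mean over both groups, stood at 0.22 (adjusted p = 0.343). Of 3 genes of the plastid isoprenoid pathway, DXS (-0.80) and HDS (-1.60) fell and CMK stood at -0.35 in the authors' deposited table.

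Photosynthetic electron transport and carbon fixation genes were mostly lower. The authors' deposited table called 5 of 6 electron transport genes lower (Fisher's exact test adjusted p = 0.36), among them PetJ, cytochrome c6 (-5.81), OEE3 (-5.78), PsbM (-4.05) and PsbO of the oxygen-evolving complex (-1.64). petC, the other one and named after its value was seen, stood at 0.69 and was not called in the authors' deposited table. It is the only member with recovered reads, and limma's fit called it higher with all libraries and without starved library C. Adjusted over the list alone, 1 member was higher and 5 lower. Of 5 Calvin cycle genes, 4 were called lower (Fisher's exact test adjusted p = 0.465), with GapC1 at -6.06, Rpe at -4.90 and the aldolase gene FbaC1 at -2.99 in the authors' deposited table. Of 8 plastid envelope transporter genes, 6 were called lower and 1 higher in the authors' deposited table (Fisher's exact test adjusted p = 0.443). Tpt1, a triose phosphate translocator and the most abundant by the mean over both groups, fell by 4.32-fold and NTT5, a nucleotide transporter, by 3.18-fold in the authors' deposited table, and the 1 higher, NTT1 (0.94), was named after its value was seen. None of these 3 shares called lower passed the test against other genes with a symbol. Of all tested symbol genes 44.2% were called lower, against 28.2% of all tested genes, in the authors' deposited table.

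**Figure D2:**
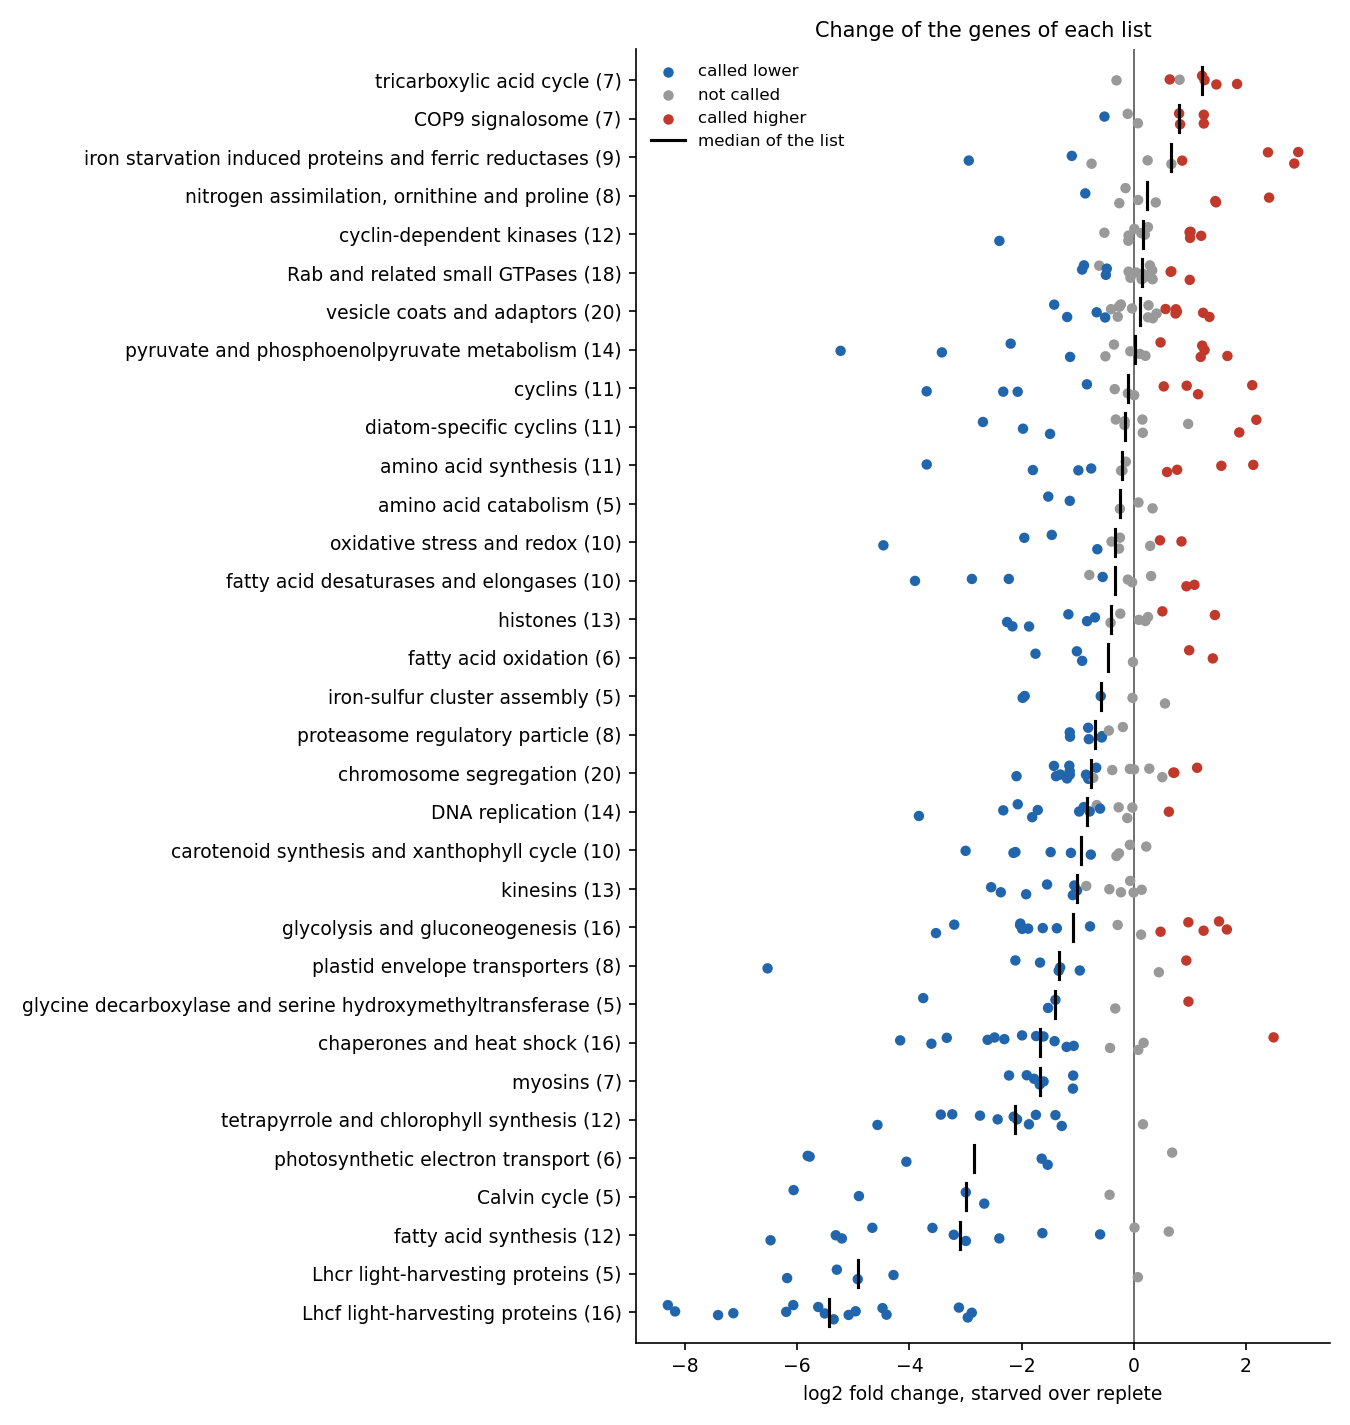
Log2 fold change (nitrogen-starved over nitrogen-replete, horizontal axis) of the genes of 33 lists named by symbol, with the number of tested genes in brackets; each point is 1 gene, coloured by its call in the authors' deposited table, and black bars are list medians. List medians run from -5.43 for the Lhcf genes to 1.22 for the tricarboxylic acid cycle.

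Carbon metabolism genes went both ways, and no list of them passed its test against other symbol genes. Of 7 tricarboxylic acid cycle genes, 5 were called higher and none lower in the authors' deposited table, with a median log2 fold change of 1.22 (99.6th percentile of random lists matched on abundance), though the share missed the threshold by Fisher's exact test (adjusted p = 0.0948). FUM1, a fumarase, rose by 3.59-fold, SCS-alpha, a succinyl-CoA synthetase subunit, by 2.78-fold and DLDH, dihydrolipoamide dehydrogenase, by 2.40-fold in the authors' deposited table. SDH1 and SDH2 of succinate dehydrogenase were also called higher in the authors' deposited table (0.64 and 1.22), and are named after their values were seen, as are OGD1 (0.82) and Fum (-0.31), the pair not called. Fum read 198, 190 and 383 in starved libraries A, B and C, and limma's fit called it lower only without starved library C. Of 16 glycolysis and gluconeogenesis genes, 5 were called higher and 9 lower in the authors' deposited table (Fisher's exact test adjusted p = 0.602 and 0.683). TPI/GapC3 (-3.53), the phosphoglycerate mutase PGAM_6 (-3.20) and PGK (-2.03) fell, while PEPCK1, phosphoenolpyruvate carboxykinase and the most abundant by the mean over both groups, rose by 0.48 (adjusted p = 0.0229) in the authors' deposited table. Of 14 pyruvate and phosphoenolpyruvate genes, 5 were called higher and 4 lower in the authors' deposited table (Fisher's exact test adjusted p = 0.48 and 0.602). PDHB1, a pyruvate dehydrogenase subunit, rose by 3.18-fold, while pDLDH1 (-3.42) and PEPCase_1 (-2.19) fell in the authors' deposited table. The glycine decarboxylase genes GDCT (-3.75), GDCP (-1.53) and GDCH (-1.40), which act in photorespiration, fell, and serine hydroxymethyltransferase SHMT rose (0.98) in the authors' deposited table. That list held 5 genes, and its share called lower did not pass the test against other symbol genes (Fisher's exact test adjusted p = 0.853).

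Most fatty acid synthesis genes were lower in starved cultures. Of 12 genes, 10 were called lower and none higher in the authors' deposited table, with a median of -3.10, below all 10000 random lists (95% between -1.55 and 0.38). The share missed the threshold against other symbol genes (Fisher's exact test adjusted p = 0.0948), and passed against all other tested genes (adjusted p = 0.00189) and where calls needed a 2-fold change (adjusted p = 0.0395), but not at adjusted p under 0.01 or with only genes of a mean of at least 50 (0.171 and 0.214). Over the 7 members with recovered reads, limma's camera called the list lower with a preset correlation of 0.01 (adjusted p = 0.0401). With an estimated correlation this call was lost (adjusted p = 0.646). The estimate was -0.127, below the preset value, so correlation among these genes cannot account for the loss. Of these 7, limma's fit called 6 lower and 1 higher, both with all libraries and without starved library C. Adjusted over the list alone, 10 of the 12 were lower and 1 was higher. FABI, enoyl-ACP reductase, fell by 39.7-fold and the acetyl-CoA carboxylase gene ACC1, the most abundant of the list by the mean over both groups, by 9.24-fold in the authors' deposited table. FABFa, a condensing enzyme, fell from 298 ± 10.2 to 8.09 ± 3.64 normalised reads (mean ± SD, n = 3). Of 10 desaturase and elongase genes, 4 were called lower and 2 higher in the authors' deposited table (Fisher's exact test adjusted p = 1 for both). The elongase ELO6b_2 fell by 14.9-fold, the desaturase PTD5b rose by 2.12-fold and the abundant PTD5a fell by 1.47-fold (adjusted p = 0.0132) in the authors' deposited table. Of 6 fatty acid oxidation genes, 2 were called higher and 3 lower in the authors' deposited table, with ACD1, an acyl-CoA dehydrogenase, at 0.99 and HAD2 at -1.75 (Fisher's exact test adjusted p = 0.825 and 1).

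Nitrogen metabolism genes with a symbol went both ways. Of 8 genes of nitrogen assimilation, ornithine and proline, 3 were called higher and 1 lower in the authors' deposited table (Fisher's exact test adjusted p = 0.605 and 0.36). The 3 were CPS-II, GltX (1.47, adjusted p = 0.00125) and GltD (1.45, adjusted p = 6.45e-12) in the authors' deposited table. GLNA, glutamine synthetase, stood at -0.15 and was not called in the authors' deposited table, and P5CS of proline synthesis fell by 1.82-fold, both named after their values were seen. Of 11 amino acid synthesis genes, 4 were called higher and 4 lower in the authors' deposited table (Fisher's exact test adjusted p = 0.568 and 0.936). EPSPsy of the shikimate pathway rose by 4.38-fold in the authors' deposited table. TRPB, tryptophan synthase beta, fell from 373 ± 28.5 to 28.9 ± 5.85 and cysK, a cysteine synthase, from 287 ± 35.4 to 82.5 ± 36.1 normalised reads (mean ± SD, n = 3). Of the genes with the symbol CysK, PHATRDRAFT_54915 was called higher (1.56) and PHATRDRAFT_bd542 lower (-0.99) in the authors' deposited table, both named after their values were seen. METH, the most abundant of that list, had a log2 fold change of -0.23 (adjusted p = 0.370) in the authors' deposited table. Of 5 amino acid catabolism genes, MMSDH (-1.52) and SSDH (-1.14) were called lower and none higher in the authors' deposited table (Fisher's exact test adjusted p = 1 for lower).

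Genes of DNA replication and mitosis were mostly lower. Of the 6 MCM helicase genes, the cell cycle and replication genes that the fixed pattern matched, 5 were called lower in the authors' deposited table and 5 adjusted over the list alone, a share that did not pass Fisher's exact test against other symbol genes (adjusted p = 0.159) and passed against all tested genes (adjusted p = 0.0165). MCM4 fell from 379.6 ± 32.6 to 26.7 ± 8.63, MCM5 from 146 ± 32.5 to 34.7 ± 11.6 and MCM3 from 368 ± 73.2 to 105 ± 36.6 normalised reads (mean ± SD, n = 3). MCM2, the other one and named after its value was seen, read 86.7, 90.5 and 215 in starved libraries A, B and C against 133 ± 28.1 in replete ones (mean ± SD, n = 3), and limma's fit called 5 MCM genes lower with all libraries and 6 without starved library C. Of 14 DNA replication genes, 9 were called lower and 1 higher in the authors' deposited table (Fisher's exact test adjusted p = 0.465), with POLA at -2.33 and PCNA, the sliding clamp, at -1.71, and the 1 higher, RFC3 (0.63), named after its value was seen. Of 20 chromosome segregation genes, 11 were called lower and 3 higher in the authors' deposited table (Fisher's exact test adjusted p = 0.602). The condensin gene SMC2 fell by 4.26-fold in the authors' deposited table, and CDC20_1, an activator of the anaphase-promoting complex, fell from 247 ± 19.2 to 94.7 ± 20.1 normalised reads (mean ± SD, n = 3).

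All 7 myosin genes were called lower in the authors' deposited table (median log2 fold change -1.68), as were 7 of 13 kinesin genes, whose products move along microtubules. The myosin share missed the threshold against other symbol genes (Fisher's exact test adjusted p = 0.0699) and passed against all tested genes (adjusted p = 0.00189) and where calls needed a 2-fold change (adjusted p = 0.00929), but not at adjusted p under 0.01 or with only genes of a mean of at least 50 (0.443 and 0.214). Over the 5 myosin genes with recovered reads, limma's camera did not pass with either correlation (adjusted p = 0.114 preset and 0.785 estimated). The kinesin share passed against neither background (Fisher's exact test adjusted p = 0.811 and 0.196). myoC3, the most abundant myosin gene, fell by 3.20-fold in the authors' deposited table, and myoA3 fell from 128 ± 16.9 to 37.2 ± 20.4 normalised reads (mean ± SD, n = 3). Pt-KIF4 fell from 128 ± 24.1 to 33.9 ± 22.8 and Pt-KiF14 from 85.9 ± 8.92 to 16.6 ± 10.7 normalised reads (mean ± SD, n = 3). Pt-KIF3, the most abundant kinesin gene by the mean over both groups, stood at 0.14 in the authors' deposited table (adjusted p = 0.678). Starved library C read lower than starved libraries A and B for 12 of the 13 kinesin genes, by a median log2 difference of -1.04 (adjusted p = 0.0036 against random lists), and for 3 of 5 myosin genes with recovered reads, by -0.85 (adjusted p = 0.0896). That comparison rests on 1 library, and its random lists take genes as independent, while camera estimated a correlation of 0.499 among the kinesin genes. The estimate used library C too, so the difference of that library enters it. In limma's fit to the recovered reads, 7 kinesin genes were lower with all libraries and 8 without starved library C, and 5 myosin genes in either fit.

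**Figure D3:**
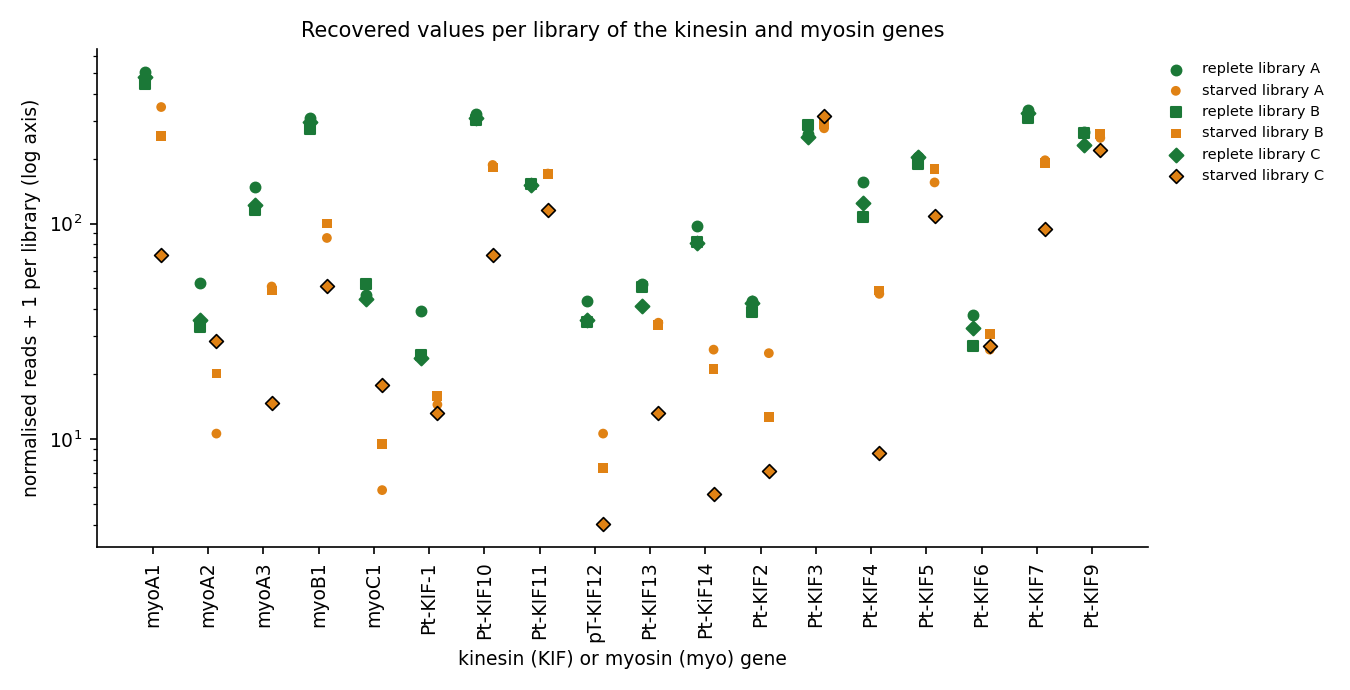
Normalised reads + 1 per library (log axis) of 18 kinesin and myosin genes, recovered from the group means; green marks are nitrogen-replete libraries, orange marks nitrogen-starved ones, and black outlines mark starved library C. For Pt-KIF4, starved library C reads 7.63 against 46.2 and 47.9 in starved libraries A and B, before 1 is added.

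Cyclin and histone genes moved in both directions. Of 11 cyclin genes, 4 were called higher and 4 lower in the authors' deposited table (Fisher's exact test adjusted p = 0.568 and 0.936), with CYCP6 up by 4.33-fold, CYCH1 down by 12.9-fold and CYCD1 down by 5.02-fold. Of 11 diatom-specific cyclin genes, 2 were called higher and 3 lower in the authors' deposited table (Fisher's exact test adjusted p = 1 and 0.602), among them dsCYC3 (1.88, adjusted p = 0.00472), dsCYC6 (-1.97) and dsCYC4 (-1.49). Of the 7 with recovered reads, limma's fit called 1 higher with all libraries and 3 without starved library C. Of 12 cyclin-dependent kinase genes, 4 were called higher and 1 lower in the authors' deposited table (Fisher's exact test adjusted p = 0.602 and 0.161). CDKA1 rose by 2.30-fold in the authors' deposited table, and hCDK4 rose from 175 ± 4.04 to 354 ± 11.1 and hCDK7 fell from 113 ± 18.6 to 21.4 ± 6.51 normalised reads (mean ± SD, n = 3). Of 13 histone genes, 2 were called higher and 6 lower in the authors' deposited table (Fisher's exact test adjusted p = 1 for both). H3-1c rose by 1.45, the abundant H3.3 by 0.51 (adjusted p = 0.0271), and H3-1b fell, at -2.16, in the authors' deposited table. H2B-1a fell from 459.8 ± 22.4 to 126 ± 36.5 normalised reads (mean ± SD, n = 3). Reads of near-identical histone copies could be split between them, so single histone values are uncertain.

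Most chaperone genes were lower. The fixed pattern matched 11 chaperone and heat shock genes, of which 9 were called lower and none higher in the authors' deposited table, and 9 adjusted over the list alone (Fisher's exact test adjusted p = 0.0415). The call was lost with only genes of a mean of at least 50 in the test (adjusted p = 0.0817), and the median of -1.99 lay at the 15.4th percentile of random lists matched on abundance. With chaperonins, BiP and the GrpE genes added, 12 of 16 were called lower and 1 higher, GrpE (PHATRDRAFT_12896), in the authors' deposited table. That share missed the threshold against other symbol genes (Fisher's exact test adjusted p = 0.161), and passed against all tested genes (adjusted p = 0.00189) and where calls needed a 2-fold change (adjusted p = 0.00929), but not at adjusted p under 0.01 or with that minimum mean (0.121 and 0.214). The small heat shock protein genes HSP20A, HSP20B and HSP20C fell by 17.9-fold, 12.2-fold and 10.1-fold, and HSP70A by 3.05-fold, in the authors' deposited table. Of 8 genes of the proteasome regulatory particle, 6 were called lower, by at most 2.20-fold (RPN6), in the authors' deposited table (Fisher's exact test adjusted p = 0.443), with RPN9 at -1.14 and the abundant RPN2 at -0.81. Of 7 COP9 signalosome genes, 4 were called higher and 1 lower in the authors' deposited table (Fisher's exact test adjusted p = 0.239 and 0.443), with CSN3 the 1 lower (-0.52, named after its value was seen), and their median of 0.81 lay at the 99.4th percentile of random lists. CSN7 rose from 59.5 ± 3.85 to 141 ± 40.2 and CSN2 from 126 ± 7.67 to 224 ± 8.13 normalised reads (mean ± SD, n = 3), and CSN6 rose by 2.38-fold in the authors' deposited table. Of 4 genes of host ER-associated degradation, hPng1 (0.71) was called higher, hUba1 (-0.67) lower, and hRad23 (-0.39) and hHrd1 (0.24) neither, in the authors' deposited table. sUbi, listed with the symbiont-derived plastid import machinery, fell by 2.63-fold in the authors' deposited table.

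Iron-related and redox genes did not move one way. Of 9 iron starvation induced and ferric reductase genes, 4 were called higher and 2 lower in the authors' deposited table (Fisher's exact test adjusted p = 0.37 and 0.602). ISIP2A, an iron uptake protein, fell from 450.2 ± 122 to 58.6 ± 7.30 normalised reads (mean ± SD, n = 3), against the rises of FRE3 and FRE4. Both families were split: ISIP1 was called higher (2.93) and FRE1 lower (-1.10) in the authors' deposited table, both named after their values were seen. Over the 7 of these genes with recovered reads, limma's fit called 4 higher and 2 lower with all libraries, and 4 and 3 without starved library C. Of 5 iron-sulfur cluster genes, IscU (-1.98), CsdB (-1.94) and sufD (-0.59) were called lower in the authors' deposited table (Fisher's exact test adjusted p = 0.853). Of 10 redox genes, 2 were called higher and 4 lower in the authors' deposited table (Fisher's exact test adjusted p = 1 for both). SOD1, a superoxide dismutase, fell by 22.1-fold, and Gsr_2, a glutathione reductase, by 2.75-fold, in the authors' deposited table, while the glutaredoxin gene GLRXM1 rose from 168 ± 16.5 to 304 ± 22.2 normalised reads (mean ± SD, n = 3). Of the 6 redox genes with recovered reads, limma's fit called 2 lower with all libraries and 4 without starved library C.

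Membrane traffic genes went both ways. Of 20 vesicle coat and adaptor genes, 6 were called higher and 4 lower in the authors' deposited table (Fisher's exact test adjusted p = 0.63 and 0.239). AP1sigma rose from 191 ± 15.8 to 487 ± 105 and AP3sigma from 47.5 ± 2.93 to 112 ± 26.8 normalised reads (mean ± SD, n = 3), while CHC, clathrin heavy chain, fell by 2.67-fold in the authors' deposited table. Of the 10 with recovered reads, limma's fit called 1 lower with all libraries and 3 without starved library C. Of 18 Rab and related GTPase genes, 3 were called higher and 4 lower in the authors' deposited table (Fisher's exact test adjusted p = 0.936 and 0.36). Rab2 rose by 2.00-fold, Sar1B fell by 1.89-fold, ARL1 by 1.85-fold, and Arf1, the most abundant by the mean over both groups, fell, at -0.48 (adjusted p = 0.0488), in the authors' deposited table. Of 4 cryptochrome and photolyase genes, CPF2 (-1.13) and CPD3 (-0.94) were called lower, and CPF1 (0.35) and CPD1 (-0.04) were not, in the authors' deposited table. CPF2 read 14.4, 6.39 and 32.1 in starved libraries A, B and C, so leaving out library C lowers its starved mean, and limma's fit called 1 of the 4 higher only without that library.

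Starved library C stood apart from the other starved libraries, while the libraries of the replete group lay close together, as did starved libraries A and B. Across 6731 recovered genes with a mean of at least 20, log2 values correlated at r = 0.973 to 0.98 between replete libraries and at r = 0.97 between starved libraries A and B, but at r = 0.896 and 0.884 between these and starved library C (genes are not independent replicates). Between groups r ran from 0.509 to 0.529. The chi-square per degree of freedom of read counts was 7.42 and 8.19 for pairs with starved library C, 2.27 for starved libraries A and B, and 1.33 to 2.46 for replete pairs. The median SD between libraries was 0.13 log2 units in the replete and 0.25 in the starved group. Fitted to 7109 recovered genes, limma placed 2209 genes higher and 2208 lower in starved cultures at an adjusted p under 0.05. Without starved library C these counts were 2573 and 2529. Of the 3738 genes that the authors' deposited table called among them, 3729 were called in the same direction by limma with all libraries.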

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

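The fit with limma, its blocks by possible pairing and counts per list, the symbol lists and the camera test with a preset correlation were added after seeing the data, and the other alternatives, its pseudocount of 0.1 and leaving out each library among them, were fixed before. Counts of called genes stayed within 1.5 times of the main counts at adjusted p under 0.01 or 0.1 and with a filter on the mean. Requiring an absolute log2 fold change of at least 1 left 1669 higher genes of 2729, and Holm adjustment left 1106 higher and 1612 lower, both by construction. Leaving out 1 library at a time, limma called from 1869 to 2573 genes higher and from 1828 to 2529 lower, with the highest counts without starved library C. Of the 4417 genes called with all libraries, 4375 were also called without that library, and 727 were called only without it. A pseudocount of 0.1 gave 2211 higher and 2195 lower. Both fixed lists called (light-harvesting proteins and chaperones) became 1 with only genes of a mean of at least 50, where the chaperones were lost, and 3 against all tested genes, with cell cycle and DNA replication added. The 2 symbol lists called (Lhcf and tetrapyrrole) became 1 with that minimum mean, 5 against all tested genes, and 6 with a 2-fold minimum, of which one, the Rab GTPases, was depleted of lower calls. Among recovered genes, camera called 1 list with a preset correlation and 0 with an estimated one (smallest adjusted p 0.646), in lists where many members are missing. The 1 list, fatty acid synthesis, was lost though its estimated correlation (-0.127) lay below the preset 0.01. The Lhcf, tetrapyrrole and chaperone lists were not put to camera, with 0, 1 and 3 recovered genes, under the minimum of 5. With the minimum mean of 50, 81.8% of the chaperone and 91.7% of the tetrapyrrole genes were still called lower, as in the main test. Those lost calls therefore came from the genes compared with or the adjustment, not from the members. The cause of the other changes was not tested. Over 134 named genes and 3 scalings, none changed sign, and 2 of the values moved by over a standard error taken from the deposited p, both with a pseudocount of 1. Small shifts of all genes alike could hardly turn a sign, so this is no test of the normalisation. Without the most abundant gene of each group, the 10 most abundant took 7.08% in replete and 7.52% in starved cultures, and the 100 most abundant 23.2% in starved ones. As a single fit, no paired analysis was possible because the recovered libraries and the group means carry no replicate numbers, so the true pairing is not known and only a range over pairings can be given. With each of the 6 possible pairings as a block, limma called from 2103 to 2153 genes higher and from 2093 to 2159 lower, and from 4145 to 4224 of the 4417 genes called without a block. Models for counts were not run, since the deposited values are group means and reads were recovered for only part of the genes. Depth limits genes with means near 1, and the most abundant genes have no spread per library here.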

Other observations

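The tests of admixture and of cell division below were chosen only after the results they measure had been seen. Across 18 symbol lists with recovered genes, starved library C was compared with starved libraries A and B, and 1 list, the kinesins, passed the test. The random lists take genes as independent, while camera estimated a correlation of 0.499 among the kinesin genes. Library C was among the libraries used for that estimate, so its difference enters the value. The comparison also rests on 1 library, so its p-values do not measure the spread between cultures. Kinesin genes were lower in it by a median log2 difference of -1.04 (12 of 13 genes, adjusted p = 0.0036 against random lists matched on abundance, from the smallest p that 10000 random lists can give). Histone genes (-0.62), diatom-specific cyclin genes (-0.67) and myosin genes (-0.85) lay lower and Rab GTPase genes (0.53) higher, each with an adjusted p of 0.0896, which misses the threshold. Of 3952 genes with a mean of at least 100, 303 lay over 2-fold from the other starved libraries in library C, 217 of them lower, against 33 and 57 genes for starved libraries A and B and at most 3 in a replete library. Pt-KIF4 read 7.63 normalised reads in it against 46.2 and 47.9, myoA1 70.2 against 345.7 and 253.3, and H1 41.2 against 137.7 and 127.7, genes chosen after their values were seen.

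Of the explanations weighed for that library, the tables argue against its lower depth as the cause: after the other starved libraries were thinned to its depth, they still correlated at r = 0.961, above 0.896. Admixture of replete cells or reads moves genes only towards their replete level: of the 217 genes over 2-fold lower in it, 47.9% lay that way and 113 genes did not, against 57 genes over 2-fold either way in starved library B, which argues against admixture as the whole cause for these genes. Of the 86 genes over 2-fold higher in it, 81.4% lay towards the replete level. The 20 genes lowest in starved libraries A and B against replete ones had there a median of 2.52% of the replete level. In library C these 20 genes stood at a median of 2.73% (upper limit 4.10%). A share of replete reads up to that limit can raise only 5.81% of the 86 genes 2-fold, which argues against admixture as the whole cause there too. A smaller admixture stays open for genes that fell at least 8-fold, since 57.0% of 135 such genes were higher in it and 58 were not. Fewer dividing cells in that culture may lower its kinesin and myosin genes (median -0.95 over 18 genes), but these were picked for being low in it, the MCM genes of DNA replication were split, 4 higher and 2 lower, with a median of 0.73 at the 99.9th percentile of random lists, and no measure of division was used here, so this stays open.

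Changes of genes next to each other on a chromosome were weakly correlated. The correlation of log2 fold changes across 8396 adjacent pairs was r = 0.165 (adjusted p = 0.003, from the smallest p that 1000 permutations can give, over 6 distances). Genes 2 places apart gave 0.0576, above the permuted range (up to 0.0237, permutation adjusted p = 0.003), while genes 3 places apart gave 0.0074, inside the permuted range. Reads of overlapping neighbours counted for both could give a correlation of adjacent genes, and the value at 3 places (0.0074) leaves that open. Such reads alone need no correlation at 2 places, and with no strand or overlap known here, shared reads and shared regulation, which was not tested, cannot be told apart. Runs of called genes in one direction reached 7 genes, within the range of permuted orders (up to 9).

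Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes called by limma, the real one with 4417 (4689 at an unadjusted p under 0.05), and the highest of the others gave 0 (82 at an unadjusted p under 0.05). The splits are too few for a share under 0.05. The others also put replete and starved libraries on both sides. The nitrogen difference then enters their residual spread, so few calls follow whatever the cause.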
